A study of Homo sapiens with 49 samples.

How the data were processed

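Total RNA from frozen human brain tissue was sequenced in 49 libraries: 14 of the Control group, 10 of the PWE group and 25 of the RE group. Per the labels, RNA was extracted with a miRNeasy kit (Qiagen), stranded libraries were made after depletion of ribosomal RNA, and paired-end reads were sequenced on an Illumina NovaSeq instrument. The authors converted the base calls with bcl2fastq and aligned the reads with STAR to the hg38 build. The versions of both tools, the counting program, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per gene symbol, without normalization, 1 library per file, and every file lists the same 60591 features. They were checked to be whole numbers whose totals differ between libraries. Groups were taken from the labels, which give neither brain region, nor donor, nor batch. For 4 libraries the stated library name differs from the sample title.

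The total count per library was 9.31 to 27.6 M in Control, 10.2 to 33.1 M in PWE and 0.392 to 33.2 M in RE. Without the shallowest library, RE replicate 12, the RE range was 10.0 to 33.2 M. Feature symbols were matched to GENCODE release 29 on GRCh38, 55144 by name and 1315 through gene identifiers. Another 4132 features had no match. Positions and gene classes come from that match. Y-linked genes, XIST and TSIX, 505 features in all, were left out of every test because the donors are human.

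Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, which left 23487 genes, of which 15698 are annotated as protein-coding. Library sizes were scaled by trimmed mean of M values (TMM). All 49 libraries entered 1 quasi-likelihood fit (glmQLFit) with the group as the only factor, and each of the 3 comparisons was tested with glmQLFTest. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 changes were derived from the log2 change and its F statistic. The common biological coefficient of variation was 0.533 and the prior degrees of freedom were 3.03. In simulated counts with the same sizes and spread, 100 genes each were changed 2-fold or 4-fold. The test recovered 61% and 92% of them in RE vs Control, 48% and 92% in RE vs PWE, and 42% and 90% in PWE vs Control.

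Gene lists of cell types and pathways of brain and immune tissue, 52 with at least 5 tested members, were written from textbook knowledge. Each was tested with camera in limma 3.58.1 on log2 CPM (counts scaled to library size, prior count 2) with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry stand beside it. The score of a library on a list is the mean log2 CPM of the tested members. Differences of scores between groups, of their spread, and of 5 measures of library composition were tested with two-sided permutation tests of 100000 resamples (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). The 156 score differences were adjusted together. Within RE, 15 relations between scores were tested by Pearson r and Spearman rho with permutation p.

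The comparisons, tests, lists and alternatives were fixed before the data were examined, and so was the rule for naming genes. The rule takes 30 focal genes whatever their result, the 6 genes of smallest p in each direction of each comparison (protein-coding, mean CPM of at least 1), and up to 4 members of each list called. Of the genes it takes, a few are not reported here by name. Y-linked genes, XIST, variable segments of immune receptors and genes that are often deleted in the germline were left out of the last 2 parts.

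The alternatives were relative log expression factors, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of CPM of at least 1 in 10 libraries, protein-coding genes only, and a fit of only the 2 groups compared. Others left out the 4 libraries of separate name, or libraries whose total was under 0.5 of the median, which left out RE replicate 12. Covariates tried were the mitochondrial share, 2 surrogate variables (sva 3.50.0), and the scores of neurons and microglia, and a minimum fold of 1.5 (glmTreat) was also tried. Scores were also taken as the median of the members, and relations as partial correlations given the mitochondrial share. A myelin score as covariate, and leaving out each library in turn, were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.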

Results

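Frozen brain tissue of 3 groups was compared by RNA sequencing: 25 libraries of Rasmussen encephalitis (RE), a chronic inflammatory brain disease with seizures, 10 libraries of a group the labels call PWE, and 14 control libraries (Control). The labels do not spell out PWE. The median total count was 13.6 M per library in Control, 23.9 M in PWE and 15.3 M in RE. RE replicate 12 was far shallower than the rest, with 391964 counts and 11116 genes detected, and the counts of changed genes are given without it as well. PWE libraries held more counts than Control libraries (mean 22.0 against 15.5 M, permutation p = 0.0267, adjusted p = 0.2). The median mitochondrial share of counts was 3.56% in Control, 3.01% in PWE and 3.94% in RE. The labels do not say whether the libraries come from separate donors, so the p-values measure the spread between these samples. Positions are on GRCh38, and values after ± are standard errors unless given as SD.

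RE vs Control asked how brain tissue in Rasmussen encephalitis differs from control tissue. Genes of microglia, the resident macrophages of the brain, were higher in RE. GPR34, a microglial receptor (chromosome X, 41688973 to 41697277), rose 9.04-fold (log2 change 3.18 ± 0.38, n = 25 and 14, adjusted p = 1.89e-07) and was above the Control median in 25 of 25 RE libraries. TMEM119 (chromosome 12, 108589846 to 108598320) rose by 2.76 ± 0.36 on the log2 scale (24 of 25 libraries) and P2RY12, a purinergic receptor of microglia (chromosome 3, 151337380 to 151384812), by 2.19 ± 0.38 (25 of 25). Of 14 tested genes of the Homeostatic microglia list 13 rose, also 13 adjusted over the list alone, and 1 did not pass. The score of this list was 5.39 ± 0.83 (SD, n = 25) in RE and 3.27 ± 0.90 (SD, n = 14) in Control, a difference of 2.12 (permutation test, adjusted p = 0.00104), and its camera call had an adjusted p = 0.0455 with an estimated correlation.

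Activated microglia and macrophage genes rose in part, 14 of 25 (16 adjusted over the list alone; 17 by DESeq2 and 20 by voom). TREM2, a lipid-sensing receptor, rose by 3.21 ± 0.51 and AIF1, a macrophage marker, by 2.03 ± 0.42. LILRB4, an inhibitory receptor of myeloid cells, rose by 3.24 ± 0.38 in 25 of 25 libraries. The score difference was 1.58 (adjusted p = 0.00117), and camera gave an adjusted p = 0.24 with an estimated correlation. CD163, a scavenger receptor named after its values were seen, was the member that fell (by 2.31 ± 0.70), where DESeq2 and voom called 0 lower and 1 was lower at an unadjusted p under 0.05, and without Control replicate 9 the count of members that fell was 0. Of the MHC class II presentation list 15 of 16 genes rose (15 adjusted over the list alone), with a median log2 change of 2.98 (adjusted p = 0.24 with an estimated correlation). CD74, the invariant chain, rose 12.3-fold (3.62 ± 0.63, adjusted p = 8.75e-05, 24 of 25 libraries) and HLA-DRA 13.7-fold (3.78 ± 0.69, 23 of 25). Of 18 MHC class I presentation genes 13 rose (14 adjusted over the list alone; adjusted p = 0.455 with an estimated correlation), among them B2M (2.05 ± 0.44, 23 of 25). Of 22 Complement genes 9 rose by edgeR, 10 by DESeq2 and 16 by voom, with C3 (chromosome 19, 6677704 to 6730562) 8.10-fold higher (3.02 ± 0.45, 25 of 25) and C1QA higher by 1.84 ± 0.52 (adjusted p = 0.0106; 2.89 without Control replicate 9). By edgeR 3 fell, among them C7 and CD59, named after their values were seen, against 2 by DESeq2 and 0 by voom (3 lower at an unadjusted p under 0.05), and without Control replicate 9 the number that fell by edgeR was 1. Complement had an adjusted p = 0.455 with an estimated correlation and a score difference of 1.13 (adjusted p = 0.0197). Among astrocyte genes GFAP rose by 1.87 ± 0.56 (adjusted p = 0.0149, 20 of 25). Of 19 Reactive astrocyte genes 2 rose and 2 fell by edgeR (4 and 3 by DESeq2, 9 and 1 by voom). The score of that list differed by 0.69 without passing (permutation test, adjusted p = 0.237). AQP4, a water channel, was higher by 0.89 ± 0.33 (adjusted p = 0.0424), a call lost without any of Control replicates 1 to 7, 13 and 14 or RE replicates 2, 3, 10, 17, 22 and 23 (adjusted p up to 0.0738). CHI3L1 (0.79 ± 0.74) and SLC1A2 (0.06 ± 0.39) did not pass.

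T cell and cytotoxic lymphocyte genes were higher in RE than in Control. Of 21 T cell genes 14 rose (adjusted over the list alone 15 rose and 1 fell), with CD3E, a chain of the T cell receptor complex, up 17.5-fold (4.13 ± 0.77, adjusted p = 0.000233, 24 of 25 libraries). Of 18 Cytotoxic lymphocyte genes 12 rose (15 adjusted over the list alone), with a median log2 change of 2.43. CCL5, a chemokine of activated T cells (chromosome 17, 35871491 to 35880793), rose 30.1-fold (4.91 ± 0.77, adjusted p = 2.37e-05, 25 of 25). The killing proteins GZMB (3.20 ± 0.83, 21 of 25) and PRF1 (2.46 ± 0.71, 20 of 25) rose, while CD8A did not pass (0.76 ± 0.30, adjusted p = 0.0586). The scores of both lists were higher in RE, by 1.21 for T cells (adjusted p = 0.0294) and by 1.54 for cytotoxic lymphocytes (adjusted p = 0.0104, 24 of 25 libraries). Camera gave an adjusted p = 0.455 with an estimated correlation for the T cell list and 0.354 for the cytotoxic list. Of 14 checkpoint and residency genes 12 rose (12 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), with ZNF683, a transcription factor of tissue-resident T cells (chromosome 1, 26361634 to 26374522), 60.8-fold higher (5.93 ± 1.02, adjusted p = 7.55e-05, 22 of 25). ZNF683 and GZMB averaged 1.71 and 0.789 CPM over all libraries, so the sizes of their changes are ratios to low counts. CXCL9, an interferon-induced chemokine, rose by 5.62 ± 1.17 (21 of 25), and CXCL10 did not pass (1.65 ± 1.03). Of 17 genes of the Chemokines list, which includes CCL5, 7 rose and 5 fell by edgeR (8 and 1 by DESeq2, 8 and 1 by voom). Its score difference of 0.71 did not pass (permutation test, adjusted p = 0.15). Of 16 Type II interferon response genes 7 rose (8 adjusted over the list alone), with an adjusted p = 0.544 with an estimated correlation. The score difference of this list, 1.08, did not pass (permutation test, adjusted p = 0.109). Markers of blood were higher in RE than in Control too. Of 6 Neutrophil genes 4 rose (FCGR3B, CSF3R, CXCR2 and LTF, camera adjusted p = 0.335 with an estimated correlation). Of 5 Erythrocyte genes 4 rose (2 by DESeq2 and 3 by voom, camera adjusted p = 0.455 with an estimated correlation), of which 1 remained without RE replicate 12. Both scores were higher in RE, by 1.155 for neutrophils and 1.618 for erythrocytes (permutation test, adjusted p = 0.0134 and 0.0248).

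The score of Inhibitory interneuron genes was lower in RE than in Control, and the number of its genes that passed differed between tools. Of 22 tested 18 fell by voom, 4 by DESeq2 and 4 by edgeR (4 adjusted over the list alone; 8 lower at an unadjusted p under 0.05). The 4 by edgeR were RELN (-1.50 ± 0.44), VIP (-1.64 ± 0.50), CRH (-1.70 ± 0.54) and CCK (-1.33 ± 0.48), and 2 fell without Control replicate 4. Calls were lost for CRH without Control replicate 4 (adjusted p = 0.0538) and for CCK without Control replicates 1, 3, 4, 6, 11 or 14 (up to 0.0642). The score was 1.97 ± 1.84 (SD) in RE and 3.61 ± 1.04 (SD) in Control (difference -1.64, adjusted p = 0.0293, lower in 19 of 25 libraries), and camera gave an adjusted p = 0.527 with an estimated correlation. GAD1 (-0.75 ± 0.45), SST (-0.95 ± 0.58) and PVALB (-0.91 ± 0.56) did not pass. Neither did the neuronal genes SNAP25 (-1.21 ± 0.49, adjusted p = 0.0646), SYN1 (-0.41 ± 0.48), SLC17A7 (-0.65 ± 0.48) and GRIA3 (-0.44 ± 0.28), nor FOS (0.02 ± 0.48). The sodium channel gene SCN1A was lower (-0.88 ± 0.32, adjusted p = 0.0388), a call lost without Control replicates 1, 3, 4, 6, 7 or 14 or RE replicates 9, 11, 22 or 23 (up to 0.0749). The Pan-neuronal score differed by -1.48 without passing (adjusted p = 0.0625), and passed without Control replicates 8 or 9 or RE replicates 1, 4, 7, 8, 19 or 20 (from 0.0295). The myelin score was higher in RE by 1.27 without passing (adjusted p = 0.109, 17 of 25), and MBP, a myelin protein, did not pass (0.49 ± 0.63). By edgeR 0 of the 20 myelin genes rose (6 higher at an unadjusted p under 0.05, 7 by DESeq2 and 1 by voom; 2 without Control replicate 10 or PWE replicate 2).

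Genes of other neuronal lists fell in RE, in numbers that differed between tools. Of 20 Pan-neuronal genes 4 fell by edgeR (2 adjusted over the list alone; median -0.93), 6 by DESeq2 and 18 by voom, and 12 were lower at an unadjusted p under 0.05, with ENO2, a neuronal enolase, at -0.94 ± 0.29 (lower in 24 of 25 libraries) and STMN3 at -0.94 ± 0.30 (23 of 25). The count by edgeR was 2 without Control replicates 1, 3, 4, 6, 10, 13 or 14 or RE replicates 11, 22, 23 or 24, 7 without Control replicate 8 or RE replicates 1, 7 or 19, and 8 without Control replicate 9. Of 20 Excitatory neuron genes 4 fell by edgeR (2 adjusted over the list alone), 4 by DESeq2 and 11 by voom, with 9 lower at an unadjusted p under 0.05, and 1 or 2 fell by edgeR without Control replicates 1 to 4, 6, 10, 11, 13 or 14 or RE replicates 2, 3, 9, 10, 11, 14 to 18 or 22 to 25. Scores that passed were Excitatory neuron (difference -1.40, adjusted p = 0.045, lower in 19 of 25), GABA-A receptor (-1.34, 0.0457, 19 of 25), Voltage-gated sodium and calcium channels (-1.24, 0.0438, 21 of 25), Potassium and HCN channels (-1.37, 0.0407, 21 of 25) and Postsynaptic scaffold (-0.88, 0.0407, 21 of 25). Each of these 5 calls was lost without Control replicates 1 to 4, 6, 13 or 14 or RE replicates 9, 10, 14, 15, 18 or 22, left out alone. All but Postsynaptic scaffold were also lost without Control replicates 10 or 11. The first 3 were lost too without Control replicates 7 or 12, PWE replicate 8 or RE replicates 2, 3, 23 or 24, and Excitatory neuron without RE replicate 12 (adjusted p up to 0.0776). Camera gave an adjusted p = 0.544 with an estimated correlation for each of these lists.

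Scores of an energy list and of markers of other brain regions were lower in RE than in Control too. The Nuclear oxidative phosphorylation score differed by -0.41 (adjusted p = 0.0457, lower in 20 of 25), and 10 of its 23 genes fell by edgeR (14 adjusted over the list alone), 10 by DESeq2 and 17 by voom, with 4 by edgeR without Control replicates 3 or 4. Camera gave an adjusted p = 0.544 with an estimated correlation. The score call was lost without Control replicates 1 to 4, 6, 7, 10, 11, 13 or 14, PWE replicate 8 or RE replicates 3, 9, 10, 11, 13 to 18 or 22 to 25 (up to 0.096). The score of Other brain region markers differed by -0.66 (adjusted p = 0.0436, lower in 22 of 25), a call lost without Control replicates 1 to 4, 6, 7 or 11 to 14, PWE replicate 8 or RE replicates 2, 9, 10, 14, 15, 18, 22 or 23 (up to 0.0703). Camera gave an adjusted p = 0.624 with an estimated correlation. Of its 11 genes 2 fell by edgeR (2 adjusted over the list alone; 2 by DESeq2 and 4 by voom), ZIC1 (-1.12 ± 0.36) and TPH2 (-1.31 ± 0.47), named after their values were seen, and 1 fell without Control replicates 1, 3, 4, 6 to 9, 11 or 14.

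Chaperone genes were lower in RE than in Control. Of 20 Heat shock and unfolded protein genes 13 fell (16 adjusted over the list alone; 13 by DESeq2 and 9 by voom), and the score was lower by 0.66 (difference -0.66, adjusted p = 0.0185, lower in 22 of 25 libraries; camera adjusted p = 0.415 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum (chromosome 9, 125234853 to 125241330), fell by 0.85 ± 0.14 on the log2 scale (adjusted p = 2.76e-05) and was below the Control median in 25 of 25 RE libraries. HSPH1 fell by 1.24 ± 0.28 and HSP90AA1 by 0.65 ± 0.17. Some genes of contractile vessel cells were lower: of 14 Pericyte and smooth muscle genes 6 fell (6 adjusted over the list alone; 5 by DESeq2, while by voom 4 fell and 2 rose), with DES, a muscle filament, at -5.15 ± 0.70 and ACTA2 at -2.27 ± 0.47 (score difference -0.72, adjusted p = 0.0277, lower in 21 of 25; camera adjusted p = 0.599 with an estimated correlation). Without Control replicate 9 these changes were smaller (DES, RE vs Control: -2.51; ACTA2, RE vs Control: -1.25). NARF (chromosome 17, 82458180 to 82490537) fell by 0.50 ± 0.07 (adjusted p = 5.4e-06, lower in 24 of 25).

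By edgeR 2834 genes were higher and 2819 lower in RE than in Control (3179 and 3101 without RE replicate 12), of which 1642 and 2393 are protein-coding. With relative log expression factors 62.1% of changed genes were higher, against 50.1% with TMM. The number of lower genes was 1727 without Control replicate 3 and 1760 without Control replicate 4. Camera called 38 of 52 lists, of which 1 held with an estimated correlation, and fry, which asks whether members move on balance 1 way without comparing them with other genes, called 26.

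**Figure D1:**
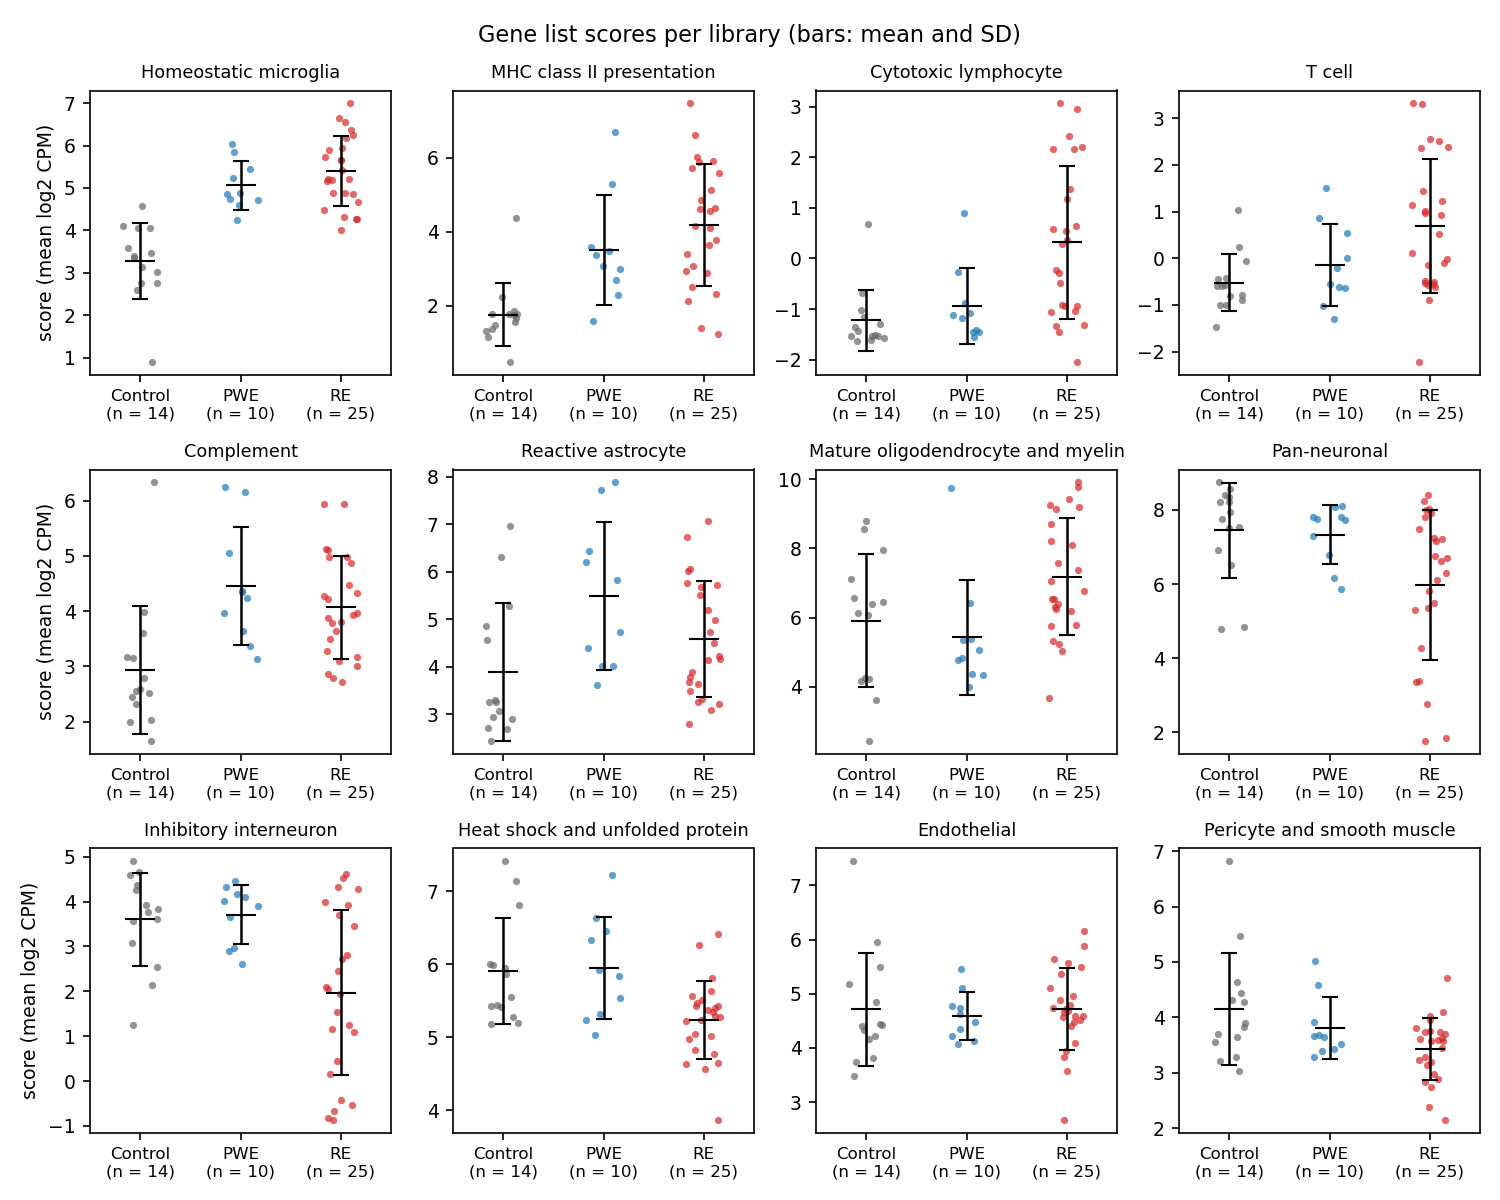
Scores of 12 gene lists (mean log2 CPM of the tested members) per library in Control (n = 14), PWE (n = 10) and RE (n = 25), with points for libraries and bars for the mean ± SD. The Homeostatic microglia score of RE (5.39 ± 0.83) and of PWE (5.06 ± 0.57) lay above that of Control (3.27 ± 0.90).

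RE vs PWE asked what sets RE apart from the PWE group. Some genes of cytotoxic lymphocytes were higher in RE. KLRD1, a receptor of NK cells and cytotoxic T cells (chromosome 12, 10226058 to 10329600), rose 6.62-fold (2.73 ± 0.55, n = 25 and 10, adjusted p = 0.00534) and lay above the PWE median in 25 of 25 RE libraries. KLRK1 rose by 2.57 ± 0.58 (adjusted p = 0.0146, 24 of 25) and ZNF683 by 4.36 ± 0.99 (adjusted p = 0.0165, 22 of 25; 6.63 without PWE replicate 6). These 2 genes averaged 0.818 and 1.71 CPM over all libraries, so the sizes of their changes rest on low counts. In the PWE libraries other than replicate 6 the log2 CPM of ZNF683 was -3.137 to -2.293. Of 18 Cytotoxic lymphocyte genes 6 rose (15 adjusted over the list alone; 11 by DESeq2 and 9 by voom), with a median log2 change of 2.47 and an adjusted p = 0.24 with an estimated correlation. The count of 6 moved to 2 without PWE replicates 3, 4, 5 or 8, 3 without PWE replicate 7, 10 without PWE replicate 2 and 11 without PWE replicate 6. CCL5 (3.17 ± 0.78, adjusted p = 0.0274) lost its call without PWE replicates 3, 4, 5 or 8 (up to 0.0597). CXCL9 (4.76 ± 1.27, adjusted p = 0.0415, 16 of 25) lost it without PWE replicates 1, 3, 4, 5, 7, 8, 9 or 10 or RE replicates 5, 17 or 24 (up to 0.0838). KLRD1, KLRK1, ZNF683, CCL5 and CXCL9 no longer passed with the myelin score as covariate (adjusted p from 0.0598 for KLRD1, RE vs PWE to 0.101 for KLRK1, RE vs PWE), with log2 changes of 2.56 for KLRD1, RE vs PWE and 4.40 for ZNF683, RE vs PWE. The score difference of this list was 1.26 and did not pass (adjusted p = 0.0625, 21 of 25), but passed without Control replicate 9, PWE replicate 6 or RE replicates 1, 7, 11, 12, 19 or 21 (from 0.0411). CD3E (2.06 ± 0.75), GZMB (2.91 ± 0.90), PRF1 (1.69 ± 0.76), CD8A (0.84 ± 0.34) and CXCL10 (3.22 ± 1.31) did not pass. Of 14 T cell checkpoint and residency genes, which include ZNF683, 1 rose by edgeR (5 by DESeq2 and 1 by voom). Of 21 T cell genes 1 rose (8 by DESeq2 and 5 by voom). Neither score passed (differences 0.682 and 0.828, permutation test, adjusted p = 0.256 and 0.21). Erythrocyte genes were higher in this comparison too, 3 of 5 rising (HBB, HBA1 and HBA2, also 3 adjusted over the list alone, camera adjusted p = 0.24 with an estimated correlation). By edgeR 0 rose without RE replicate 12 or PWE replicates 1, 3, 4 or 8. The Erythrocyte score was higher in RE than in PWE by 1.73 and passed (permutation test, adjusted p = 0.0248).

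Myelin levels were higher and interneuron levels lower in RE than in PWE. The score of the 20 Mature oligodendrocyte and myelin genes was 7.18 ± 1.69 (SD, n = 25) in RE and 5.43 ± 1.67 (SD, n = 10) in PWE (difference 1.75, permutation test, adjusted p = 0.0425, higher in 24 of 25), with an adjusted p = 0.284 with an estimated correlation. With edgeR 0 of these genes passed, 5 were higher at an unadjusted p under 0.05, DESeq2 called 0 and voom called 19. MBP had a log2 change of 1.02 ± 0.73. Without PWE replicate 2 edgeR called 20 of 20 higher. The score call was lost without PWE replicates 1 and 3 to 9 or RE replicates 2, 3, 9, 10, 14, 15, 18 or 22, each left out alone (up to 0.0769). The Inhibitory interneuron score differed by -1.74 (adjusted p = 0.0381, lower in 20 of 25; camera adjusted p = 0.398 with an estimated correlation). That call was lost without PWE replicates 3, 4, 8 or 9 or RE replicates 10, 18 or 22 (up to 0.0539). None of its genes passed by edgeR (0, against 7 lower at an unadjusted p under 0.05, 1 by DESeq2 and 16 by voom). GAD1 (-1.01 ± 0.49), SST (-0.82 ± 0.64), PVALB (-0.47 ± 0.63), SNAP25 (-0.77 ± 0.55), SLC17A7 (-0.46 ± 0.54), SCN1A (-0.54 ± 0.35), GRIA3 (-0.32 ± 0.31), SYN1 (-0.51 ± 0.53) and FOS (-0.96 ± 0.51) did not pass.

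HSPA5 and HSP90B1, chaperones of the endoplasmic reticulum, were lower in RE than in PWE. HSPA5 fell by 0.83 ± 0.15 (adjusted p = 0.00131, lower in 25 of 25) and HSP90B1 by 0.58 ± 0.14 (adjusted p = 0.0241, lower in 25 of 25). These were the 2 of 20 Heat shock and unfolded protein genes that fell (12 adjusted over the list alone; 4 by DESeq2 and 7 by voom; adjusted p = 0.24 with an estimated correlation), and HSP90B1 lost its call without PWE replicates 1, 6 or 8 (up to 0.106), which left 1. Neither passed with the myelin score as covariate (HSPA5, RE vs PWE: -0.67, adjusted p = 0.0645; HSP90B1, RE vs PWE: -0.48, adjusted p = 0.224). The score difference was -0.71 (adjusted p = 0.0225, lower in 23 of 25). Of 14 Homeostatic microglia genes 1 rose by edgeR (1 adjusted over the list alone; 2 higher at an unadjusted p under 0.05, 1 by DESeq2 and 2 by voom), with an adjusted p = 0.544 with an estimated correlation. It was SIGLEC8 (1.69 ± 0.44, adjusted p = 0.0381, 23 of 25), and 0 rose without PWE replicates 1, 3, 4, 5, 7, 8 or 9 or RE replicates 5, 10 or 22 (up to 0.0733). No focal gene of microglia, antigen presentation or complement passed: P2RY12 (0.67 ± 0.40), TREM2 (0.93 ± 0.51), AIF1 (0.11 ± 0.42), CD74 (0.68 ± 0.61), HLA-DRA (0.60 ± 0.66), B2M (1.08 ± 0.47), C1QA (0.25 ± 0.55) and C3 (-0.16 ± 0.43). Among astrocyte genes GFAP (-0.32 ± 0.57), CHI3L1 (-2.24 ± 0.75, adjusted p = 0.0919), AQP4 (-0.40 ± 0.35) and SLC1A2 (0.21 ± 0.44) did not pass. Of 19 Reactive astrocyte genes 0 rose and 2 fell by edgeR (11 lower at an unadjusted p under 0.05, 3 by DESeq2 and 3 by voom). The score of that list differed by -0.90 without passing (permutation test, adjusted p = 0.18). PDE7A, a phosphodiesterase, rose by 0.83 ± 0.17 (25 of 25), and SPON2 fell by 2.62 ± 0.39 (adjusted p = 0.00011, lower in 25 of 25). PRPH, a filament of peripheral neurons (chromosome 12, 49293252 to 49298686), fell by 6.17 ± 0.77, with 15 of 25 RE libraries below the PWE median. PRPH still passed with the myelin score as covariate (PRPH, RE vs PWE: adjusted p = 0.0108), while SIGLEC8 (SIGLEC8, RE vs PWE: 0.391), PDE7A (PDE7A, RE vs PWE: 0.0986) and SPON2 (SPON2, RE vs PWE: -1.81, 0.0714) did not.

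By edgeR 108 genes were higher and 258 lower in RE than in PWE (204 and 407 without RE replicate 12). With relative log expression factors 40.7% of changed genes were higher, against 29.5% with TMM, and with the myelin score as covariate 2 genes were higher and 7 lower (9 of the 366 calls, 2.5%, held). The number of higher genes fell to between 27 and 70 without PWE replicates 1, 3, 4, 5, 7, 8 or 9 or RE replicates 10, 14, 15, 18 or 22. It was between 165 and 245 without Control replicate 9, PWE replicate 6 or RE replicates 1, 6, 12, 19 or 20, and 1497 without PWE replicate 2. The number of lower genes was between 64 and 171 without Control replicates 3, 4, 10 or 11, PWE replicates 1, 3, 4, 5 or 8 or RE replicates 11, 22 or 25. It was between 407 and 517 without Control replicate 9 or RE replicates 1, 6, 12 or 19, and 754 without PWE replicate 2. Camera called 29 of 52 lists and 0 with an estimated correlation, where fry called 5.

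**Figure D2:**
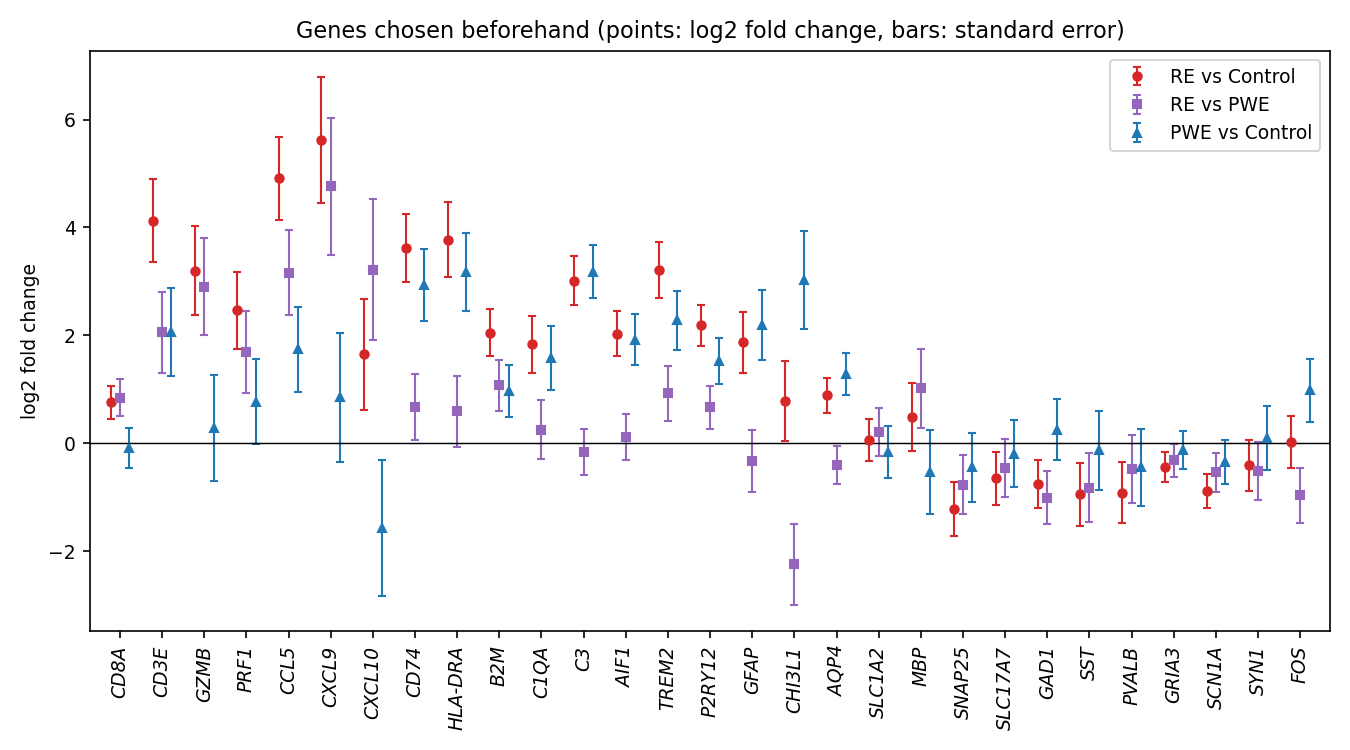
Log2 change ± standard error of the focal genes shown in RE vs Control, RE vs PWE and PWE vs Control, with points for the estimates by edgeR and bars for the standard error. The microglial and complement genes lie above 0 in both comparisons with Control (C3 3.02 in RE and 3.18 in PWE) and closer to 0 in RE vs PWE (C3 -0.16, TREM2 0.93).

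PWE vs Control asked how the PWE group differs from control tissue. Microglial genes were higher in PWE. GPR34 rose by 2.37 ± 0.40 on the log2 scale (n = 10 and 14, adjusted p = 0.000567, 10 of 10 libraries) and TMEM119 by 2.22 ± 0.39 (adjusted p = 0.000737, 10 of 10). Of 14 Homeostatic microglia genes 8 rose (12 adjusted over the list alone; 11 by DESeq2 and 12 by voom), 5 without PWE replicate 1 and 3 without PWE replicate 6. The score was 5.06 ± 0.57 (SD) in PWE, higher by 1.79 than in Control (adjusted p = 0.00104, 10 of 10), and camera gave an adjusted p = 0.0149 with an estimated correlation. P2RY12 was higher by 1.52 ± 0.43 (adjusted p = 0.0497), a call that held only without Control replicates 6, 9 or 10, PWE replicates 2 or 4 or RE replicates 1, 6, 7, 12, 13, 15, 18, 19 or 24 and was lost without any 1 of the other 35 libraries (up to 0.111).

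The complement gene C3 rose 9.05-fold in PWE (3.18 ± 0.49, adjusted p = 0.000269, 10 of 10). Chemokines of macrophages rose strongly: CCL4 (chromosome 17, 36103590 to 36105621) by 5.31 ± 0.82 and CCL3 by 4.69 ± 0.75, each in 10 of 10 libraries. Their near-identical copies CCL4L2 (4.07 ± 0.72) and CCL3L1 (4.34 ± 0.84) may share reads with them, which was not tested. These were the 4 of 17 Chemokines that rose (adjusted over the list alone 6 rose and 3 fell; 5 rose by DESeq2 and 7 by voom; adjusted p = 0.24 with an estimated correlation; score difference 1.33, adjusted p = 0.0257). CXCL1, named after its values were seen, was the member that fell (-3.98 ± 1.08; 3 lower at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom), and 0 fell without Control replicates 8 or 9 or PWE replicates 1 to 4 or 6 to 10. TNF, an inflammatory cytokine, rose by 4.31 ± 0.77 (10 of 10). Activated microglia and macrophage genes rose in 7 of 25 cases (15 adjusted over the list alone; 12 by DESeq2 and 18 by voom; adjusted p = 0.113 with an estimated correlation), a count of 4 without PWE replicate 1, 2 without PWE replicate 6, 11 without PWE replicate 2 and 16 without Control replicate 9. Of 16 MHC class II presentation genes 7 rose (14 adjusted over the list alone; 11 by DESeq2 and 7 by voom; adjusted p = 0.24 with an estimated correlation), 0 without PWE replicate 6 and 13 without Control replicate 9, while the score was higher by 1.76 (adjusted p = 0.00811, 9 of 10). CD74 (2.94 ± 0.66) and HLA-DRA (3.18 ± 0.73) lost their calls without PWE replicate 6 (adjusted p = 0.112 for each), TREM2 (2.28 ± 0.55) likewise (0.075), and AIF1 (1.92 ± 0.47) without PWE replicates 1 or 6 (up to 0.0674). C1QA (1.59 ± 0.60) and B2M (0.97 ± 0.49) did not pass.

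Of 19 Reactive astrocyte genes 3 rose in PWE by edgeR (8 adjusted over the list alone; 6 by DESeq2 and 12 by voom; adjusted p = 0.24 with an estimated correlation): C3, MAOB (2.32 ± 0.51, 8 of 10) and S100A10 (2.36 ± 0.58, 9 of 10). The count was 1 without PWE replicates 1 or 6, where MAOB (up to 0.0914) and S100A10 (up to 0.161) lost their calls, 5 without Control replicate 8 or PWE replicate 4 and 8 without Control replicate 9. The score difference of 1.59 did not pass (adjusted p = 0.0657, 10 of 10), and passed without Control replicates 8 or 9 or PWE replicates 2 or 4 (from 0.0215). Of the focal astrocyte genes GFAP (2.20 ± 0.65, adjusted p = 0.0646), CHI3L1 (3.02 ± 0.91, 0.0714), AQP4 (1.29 ± 0.39, 0.0741) and SLC1A2 (-0.15 ± 0.48) did not pass.

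Lymphocyte genes gave a mixed result in PWE vs Control. The score of T cell checkpoint and residency genes was higher in PWE by 0.86 (adjusted p = 0.0244, 10 of 10 libraries; camera adjusted p = 0.455 with an estimated correlation). By edgeR 0 of its 14 genes rose (2 adjusted over the list alone; 4 higher at an unadjusted p under 0.05, 2 by DESeq2 and 3 by voom). That 0 became 1 without PWE replicate 10 or RE replicates 1, 9 or 24, 2 without PWE replicates 2 or 4 and 4 without Control replicate 9. Of 21 T cell genes 0 rose by edgeR (2 higher and 1 lower at an unadjusted p under 0.05; 0 by DESeq2; 1 lower by voom). Likewise 0 of 18 Cytotoxic lymphocyte genes rose (2 higher and 2 lower at an unadjusted p under 0.05; 0 by DESeq2 and 0 by voom), and the median log2 change was 0.27. CD3E (2.07 ± 0.82), CCL5 (1.74 ± 0.78), GZMB (0.29 ± 0.98), PRF1 (0.77 ± 0.79), CD8A (-0.09 ± 0.36), CXCL9 (0.85, unadjusted p = 0.48) and CXCL10 (-1.57 ± 1.26) did not pass. Neuronal and myelin genes did not pass either, with SNAP25 at -0.45 ± 0.64, SLC17A7 at -0.19 ± 0.61, GAD1 at 0.25 ± 0.57, SST at -0.13 ± 0.73, PVALB at -0.44 ± 0.71, GRIA3 at -0.12 ± 0.35, SCN1A at -0.34 ± 0.40, SYN1 at 0.10 ± 0.60, FOS at 0.99 ± 0.59 and MBP at -0.53 ± 0.77. SCIN, an actin-severing protein (chromosome 7, 12570577 to 12660179), rose by 3.93 ± 0.61 (9 of 10). NARF fell by 0.50 ± 0.09 (adjusted p = 0.000938, lower in 10 of 10), about as in RE.

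By edgeR 328 genes were higher and 54 lower in PWE than in Control (375 and 94 without RE replicate 12, whose counts enter the spread). The number of higher genes was 180 without PWE replicate 1, 123 without PWE replicate 6 and 929 without Control replicate 9. The number of lower genes was between 20 and 35 without Control replicates 2 or 5 or PWE replicates 1, 6 or 8, 92 without PWE replicate 2 and 143 without Control replicate 9. Camera called 27 of 52 lists, of which 1 held with an estimated correlation, and fry called 9.

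**Figure D3:**
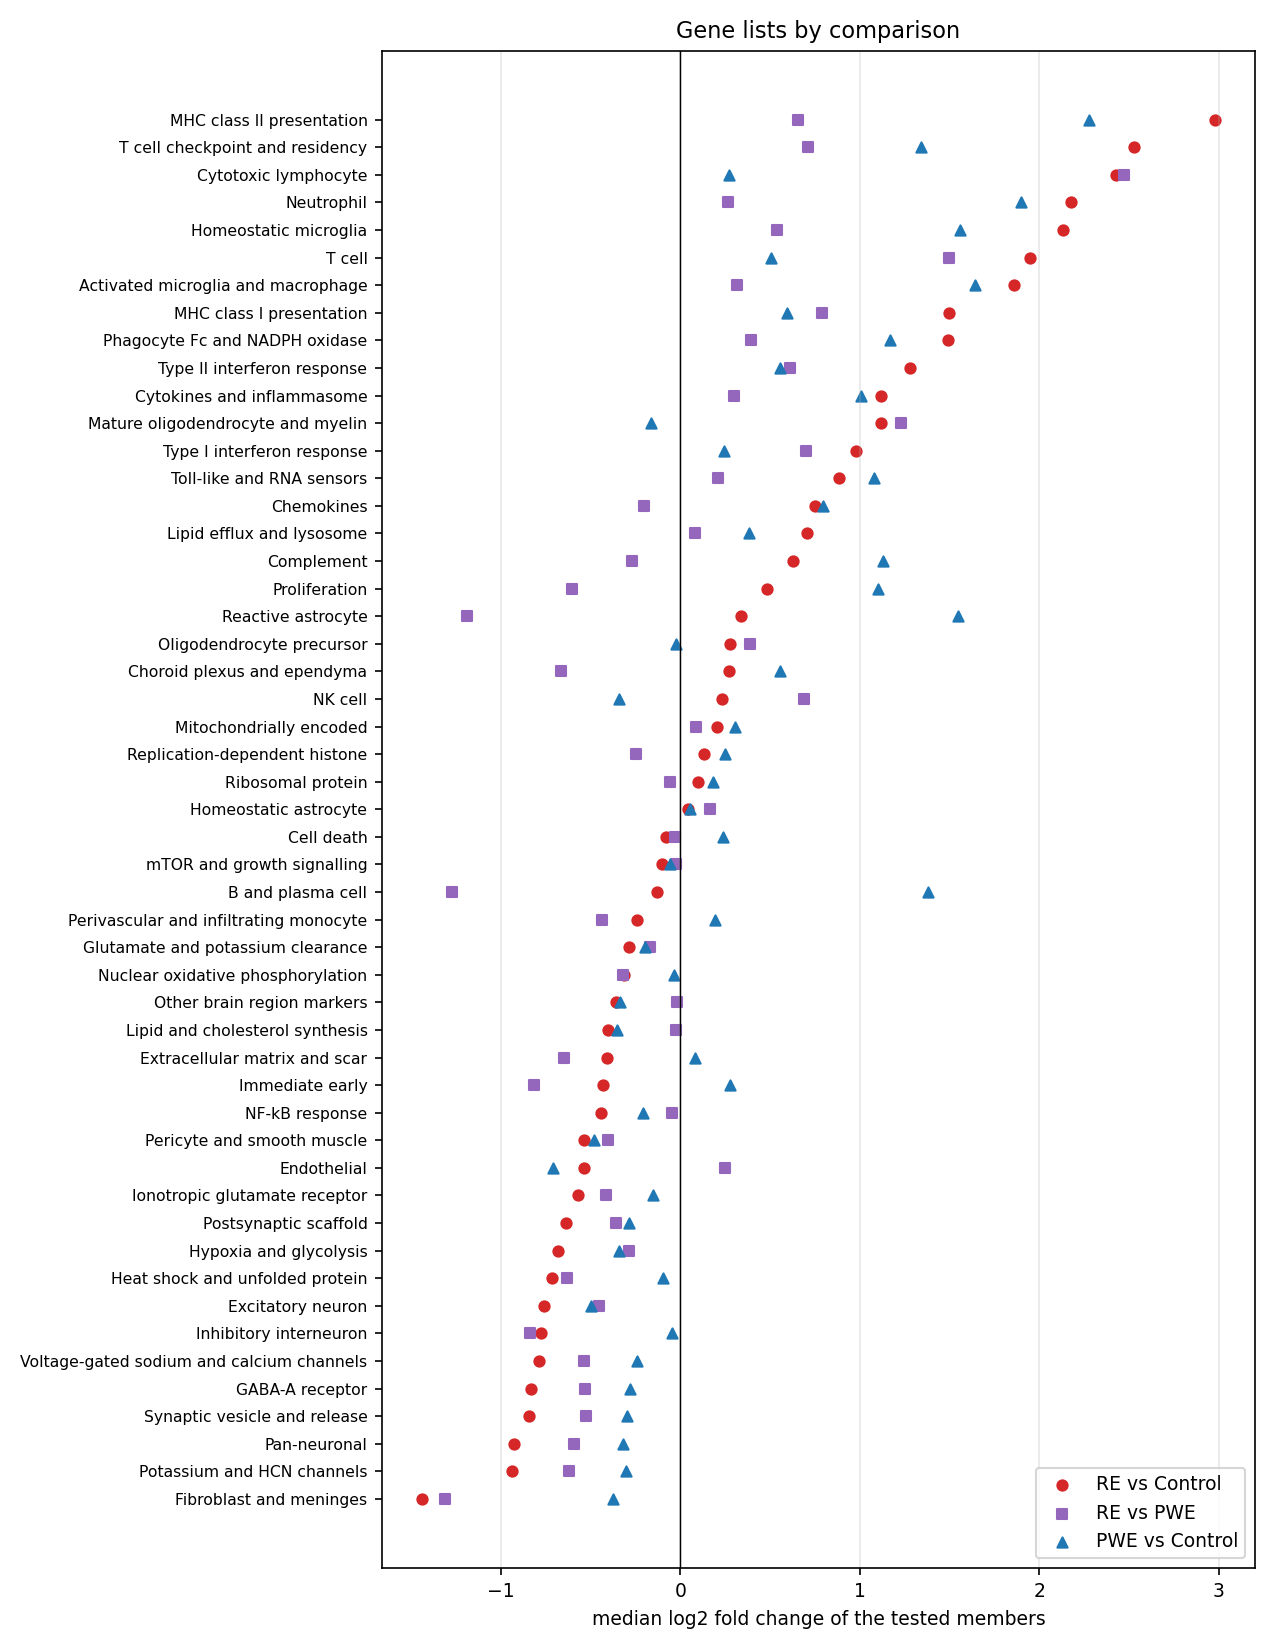
Median log2 change of the tested members of 51 gene lists in the 3 comparisons, with a point per list and comparison. The Erythrocyte list is left out because of its wide scale, and the Homeostatic microglia median is 2.13 in RE vs Control, 1.56 in PWE vs Control and 0.54 in RE vs PWE.

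Changes shared between comparisons were counted. In RE 74 genes were higher than in both other groups and 111 were lower, where independent lists of the same sizes would share 13.03 and 30.97. These counts were 2 and 0 with the myelin score as covariate. Among the genes higher than in both were KLRD1, ZNF683, CCL5, CTSW and CXCL9, and among the lower HSPA5, HSP90B1 and SPON2. None of these 8 passed in RE vs PWE with that covariate (CTSW, RE vs PWE: adjusted p = 0.0949), though the log2 changes of KLRD1 and ZNF683 given above moved little. Single libraries end the calls in RE vs PWE of CTSW (without PWE replicates 3, 4, 5, 7 or 8, up to 0.0657) and, as given above, of CCL5, CXCL9 and HSP90B1. Also higher than in both were HBB, HBA1 and HBA2, with larger log2 changes in RE vs PWE (8.475, 8.133 and 8.584). Their changes in RE vs Control reversed in sign without RE replicate 12. In RE and in PWE alike 242 genes were higher than in Control and 43 were lower, against 39.58 and 6.48 for independent lists. These included GPR34, TMEM119, C3 and CCL4 among the higher and NARF among the lower. The comparisons share a group of libraries. Where that group was split at random so that none was shared (10 runs), the medians were 8 genes higher in RE than in both, 9 lower, 33.5 higher in RE and PWE and 5.5 lower, against 2.52, 3.1, 2.7 and 0.44 for independent lists. In simulated unchanged groups the count was 0 in each of 20 runs. Genes were drawn independently there, without the joint changes of real libraries, so it gives no baseline for these counts. The 74 higher genes became 119 without RE replicate 12, 725 without PWE replicate 2, and 20 to 48 without PWE replicates 1, 3, 4, 5, 7, 8 or 9 or RE replicates 10, 14, 15, 18 or 22. They became 117 to 184 without Control replicate 9, PWE replicate 6 or RE replicates 1, 6, 7, 19 or 20. The 111 lower genes became 21 to 69 without Control replicates 3, 4, 10, 11 or 12, PWE replicates 1, 3, 4, 5 or 8 or RE replicates 11, 15, 22 or 25. They became 177 to 286 without Control replicate 9, PWE replicate 2 or RE replicates 1, 4, 6, 7, 8, 12 or 19. The 242 became 141 without PWE replicate 1, 103 without PWE replicate 6 and 722 without Control replicate 9, and the 43 became 19 to 26 without Control replicate 2 or PWE replicates 1 or 6 and 93 without Control replicate 9.

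Among the 25 RE libraries the cytotoxic lymphocyte score rose with the scores of antigen presentation and microglia. It correlated with the MHC class II presentation score at r = 0.941 (permutation p = 1e-05; rho = 0.949, p = 1e-05; r = 0.923 without the 2 libraries farthest from the median), with MHC class I presentation at r = 0.961 (rho = 0.965), with T cells at r = 0.987 (rho = 0.967) and with Homeostatic microglia at r = 0.882 (rho = 0.891), and 1e-05 is the smallest p that 100000 resamples can give. No gene is shared between the T cell and cytotoxic lists. With the myelin score it had r = 0.15 (p = 0.476; rho = 0.202, p = 0.332; r = 0.182 without the 2 libraries). The Pan-neuronal score fell as the myelin score rose (r = -0.784, p = 1e-05; rho = -0.745, p = 5e-05; r = -0.73, p = 8e-05 without the 2 libraries). Cytotoxic and Pan-neuronal scores had r = -0.465 (p = 0.0191, adjusted p = 0.0239; rho = -0.53, p = 0.00744), and r = -0.412 (p = 0.0511) without the 2 farthest libraries. Of the 15 relations tested 14 passed Benjamini-Hochberg adjustment, where the adjusted p of those at 1e-05 was 1.87e-05. Of these, 4 no longer passed given the mitochondrial share, 4 without the 4 libraries of separate name and 2 with the median of the members as score, and cytotoxic with Pan-neuronal was among them in the first 2 cases. Labels give no batch within which to repeat them.

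**Figure D4:**
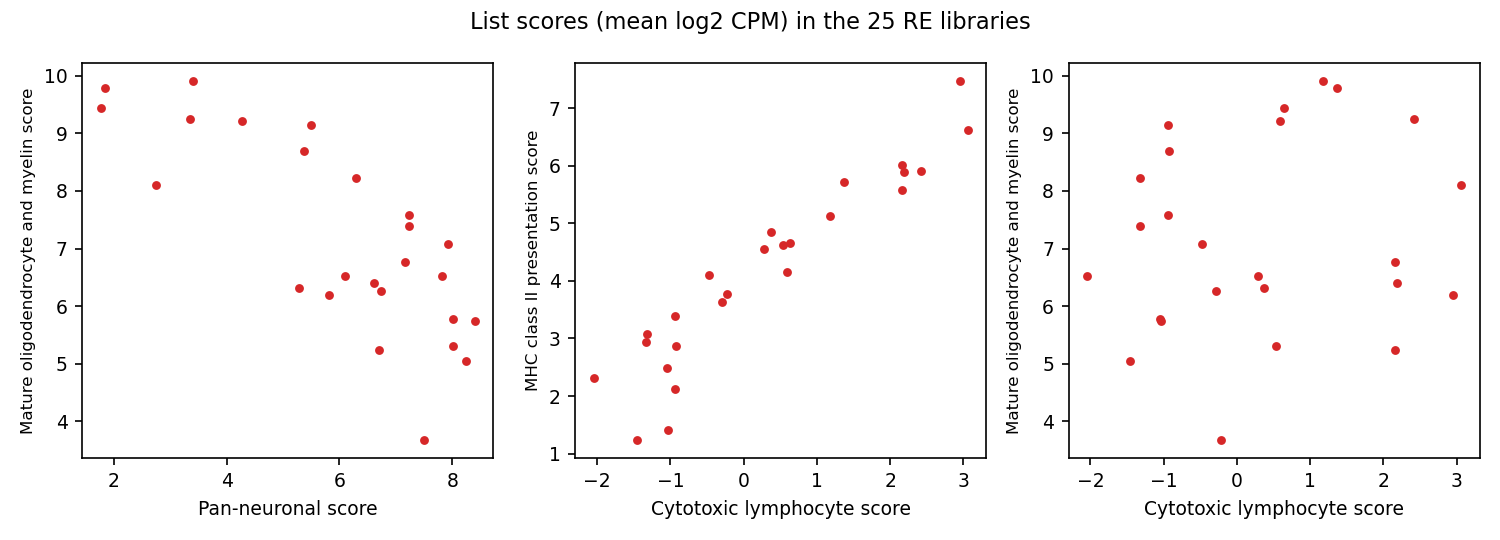
Scores of the 25 RE libraries (mean log2 CPM, 1 point per library): Pan-neuronal against myelin, cytotoxic lymphocyte against MHC class II presentation, and cytotoxic lymphocyte against myelin. Pearson r is -0.784, 0.941 and 0.15.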

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

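The tests that weigh explanations below were all chosen after the results were seen, while the comparisons with other splits of the libraries were planned before, and the tests with red cell genes were added after a joint test of blood gave no decision. In PWE, the group of 10 libraries, 237 values were searched for a library whose distance to the next one is a large share of the whole range (above the 95% critical value of Dixon for 10 samples), and 27 were found. Chance gives about 1 in 20. They were 8 of 52 list scores, 0 of 5 measures of composition and 19 of 180 genes, and 21 belonged to PWE replicate 6, 5 to PWE replicate 2 and 1 to PWE replicate 1.

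PWE replicate 6 stood highest in the scores of Cytotoxic lymphocyte (gap 0.473 of the range), T cell checkpoint and residency (0.58), B and plasma cell (0.674), Type I interferon response (0.472) and Cytokines and inflammasome (0.51), and lowest in Excitatory neuron (0.526). It was highest in ABCA13 (0.603), CD36 (0.553), COL8A1 (0.605), CXCR3 (0.555), FASLG (0.76), GZMB (0.491), IFI44L (0.582), IL16 (0.576), LTF (0.542), LUM (0.622) and ZNF683 (0.758). It was lowest in GPR17 (0.582), NLGN2 (0.497), SLC17A7 (0.561) and SV2B (0.544). PWE replicate 2 was highest in the Mature oligodendrocyte and myelin score (0.576), the mTOR and growth signalling score (0.587), ABCG1 (0.557) and MBP (0.527), and lowest in RPS23 (0.508). PWE replicate 1 was lowest in EGR3 (0.574).

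Microglial genes were higher in RE and in PWE than in Control. A lower share of neurons would raise the markers of other cell types alike, but the Homeostatic microglia score less the mean of the astrocyte, endothelial and pericyte scores was still higher in RE than in Control, by 2.236 on the log2 scale. The mitochondrial share of counts hardly differed between RE and Control (mean 5.49% and 5.22%, permutation p = 0.893). With that share as covariate 13 of the 13 genes that rose still passed. A covariate so alike in both groups could hardly change this, so the test does not decide on RNA quality, which stays open. More microglia, or more of these transcripts per cell, may underlie the pattern as a hypothesis, and these were not told apart. Brain region and handling of the tissue are not in the labels and stay open.

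Myelin scores were higher and interneuron scores lower in RE than in PWE. A lower share of neurons alone would raise astrocyte and myelin markers alike, but the myelin score less the Homeostatic astrocyte score was higher in RE by 1.71, with a permutation p above 0.05 without PWE replicate 4 or PWE replicate 9 (up to 0.0612). More white matter in the RE pieces may contribute: among RE libraries the Pan-neuronal score fell as the myelin score less the astrocyte score rose (r = -0.82; rho = -0.715; r = -0.723 without the 2 libraries farthest from the median). Loss of neurons in RE stays open beside it, and since this relation lies within RE, white matter stays open for the lower neuronal scores in RE vs Control too, as does brain region, whose markers were lower there as well.

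Cytotoxic lymphocyte genes were higher in RE than in Control and, for 6 genes, than in PWE. Blood in the tissue cannot be told apart from lymphocytes in the tissue in RE vs Control, where the Cytotoxic lymphocyte score less the Neutrophil score differed by 0.385 (p = 0.255); in RE vs PWE that measure was higher by 1.203 (p = 0.00562), which goes against blood, but it was also lower in PWE than in Control (-0.82, p = 0.00406), so the neutrophil genes, some of which microglia express too, move in PWE by themselves. With the Erythrocyte score as covariate 10 of the 12 genes that rose in RE vs Control still passed (median log2 change 2.43 before and 1.86 after). In RE vs PWE 2 of 6 still passed with it (2.47 before and 1.65 after). The calls of most Erythrocyte genes in RE vs Control were lost without RE replicate 12, as given above. The covariate fit was not repeated without that library, so it does not decide on red blood cells, which stay open in both comparisons. Among RE libraries the Cytotoxic lymphocyte score had r = -0.0426 with the Erythrocyte score (permutation p = 0.849). With the Neutrophil score it had r = 0.633 (permutation p = 0.0008, rho = 0.644), and r = 0.492 without the 2 libraries farthest from the median, which leaves blood open. A lower share of neurons as the whole cause is argued against, but only weakly in RE vs PWE. The Cytotoxic lymphocyte score less the mean of the astrocyte, endothelial and pericyte scores was higher in RE than in PWE by 1.334 (unadjusted permutation p = 0.0171). The Cytotoxic lymphocyte score alone did not pass there (permutation test, adjusted p = 0.0625). In RE vs Control the measure was higher by 1.657 (unadjusted permutation p = 0.00094). Lymphocytes in the RE tissue may be the source as a hypothesis.

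The libraries were split at random into groups of the same sizes, 100 splits with the real one. For the genes changed in RE vs Control chance is argued against (5653 genes, highest other split 1414, 1 split as large). In RE vs PWE 2 splits were as large (366 genes, highest other 694), so chance is unlikely but not excluded. In PWE vs Control chance cannot be excluded (382 genes, highest other 3066, 5 as large), and a split with several times the real count points to a structure of the samples, whose source was not tested. Camera called 38 lists in RE vs Control, where the other splits had a median of 26 and a highest of 39 (2 as large). Chance is unlikely for that number but not excluded. It cannot be excluded for the lists in RE vs PWE (29 lists, highest other 43, 31 as large) or PWE vs Control (27 lists, highest other 42, 52 as large). For the counts of genes shared between comparisons 1 split was as large in each case: 74 higher in RE than in both groups (highest other 0), 111 lower (5), 242 higher in RE and PWE than in Control (0) and 43 lower (1). These splits leave few genes changed in either comparison, so a low shared count was to be expected from them, and whether the sharing is beyond chance stays open. With the RE libraries split so that none was shared, 10 runs gave 1 to 81 genes higher in RE than in both (median 8). Those runs keep the real groups, so they give no count under chance.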

How the results depend on the processing

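The myelin score as covariate and the leaving out of each library in turn were chosen after seeing the data, and the other alternatives before. The cause of a change was not tested unless the alternative itself leaves out genes or libraries. Relative log expression factors kept the direction and the side of the threshold for 51, 52 and 52 of 52 lists in RE vs Control, RE vs PWE and PWE vs Control, and for 139, 57 and 61 of the named genes. They gave 65 genes lower in RE than in both groups.

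Counts of changed genes are given as higher and lower. DESeq2 gave 4556 higher in RE vs Control, 1006 and 560 in RE vs PWE, and 623 and 209 in PWE vs Control. Voom gave 5002 and 5085, 2765 and 2946, and 1647 and 864. With 2 surrogate variables RE vs Control had 1762 higher, RE vs PWE 186 and 819, and PWE vs Control 616 and 465, with 415 genes lower in RE than in both other groups, 427 genes higher in RE and in PWE than in Control and 296 genes lower in RE and in PWE than in Control. With the neuronal and microglial scores as covariates RE vs Control had 844 higher, RE vs PWE 132 lower and PWE vs Control 98 and 300, with 15 higher and 68 lower in RE than in both, and 80 higher and 232 lower in RE and PWE. With the myelin score they were 1707 and 1454, 2 and 7, and 133 lower in PWE vs Control, with 2 higher and 0 lower in RE than in both and 91 lower in RE and PWE. A minimum fold of 1.5 gave 558 and 150, 5 and 25, and 92 and 6.

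Without a filter RE vs PWE had 451 lower. With a CPM of 1 in 10 libraries it had 148, with 64 lower in RE than in both. With protein-coding genes only, fewer genes were tested: 146 lower in RE vs PWE, 212 higher in PWE vs Control, 56 lower in RE than in both and 152 higher in RE and PWE. With only the 2 groups compared, fewer libraries entered: 68 and 119 in RE vs PWE, 201 higher in PWE vs Control, and 24 higher and 55 lower in RE than in both. Without the 4 libraries of separate name 46 genes were higher in RE than in both, and 3 scores passed in RE vs PWE. Without libraries under 0.5 of the median total, which is without RE replicate 12, RE vs PWE had 204 and 407 and PWE vs Control 94 lower, with 119 higher and 199 lower in RE than in both.

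Camera with an estimated correlation called 1, 0 and 1 lists, and fry called 5 in RE vs PWE and 9 in PWE vs Control.

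Leaving out each library in turn gave 1727 to 3581 lower genes in RE vs Control, 27 to 1497 higher and 64 to 754 lower in RE vs PWE, and 123 to 929 higher and 20 to 143 lower in PWE vs Control. The shared counts were 20 to 725 higher and 21 to 286 lower in RE than in both, and 103 to 722 higher and 19 to 93 lower in RE and PWE. The report names the libraries that moved these. Scores passing were 25 in RE vs Control (16 to 32; 16 without Control replicates 1, 2, 4, 6, 13 or 14 or RE replicates 9, 10, 14, 15, 18 or 22), 6 in RE vs PWE (2 to 9; 3 without PWE replicates 1 or 4 or RE replicates 14 or 15, and 2 without PWE replicate 8 or RE replicates 10, 18 or 22) and 9 in PWE vs Control (8 to 19; 19 without Control replicate 9).

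Some results changed sign, and these are listed as reversed whether or not they still passed. Values in parentheses are adjusted p for lists and log2 changes for genes. No gene called in the main fit was called the other way with the mitochondrial share, the myelin score or without RE replicate 12. The same held for voom in RE vs PWE and for the neuronal and microglial scores in PWE vs Control. With those scores 6 of the 5653 genes called in RE vs Control were called the other way, and with voom 5 were. With the mitochondrial share as covariate gene list Mitochondrially encoded, RE vs PWE (0.996) and gene list Mitochondrially encoded, PWE vs Control (0.0332) reversed. With the myelin score GABA-A (0.778) and Postsynaptic (0.817) lists reversed in RE vs PWE, the myelin list in PWE vs Control (0.966) and MBP, RE vs Control (-1.198). ABCA13 reversed in RE vs PWE with voom (0.052). HBB, RE vs Control (-0.119), HBA1, RE vs Control (-0.309) and HBA2, RE vs Control (-0.738) reversed without RE replicate 12, and without each library in turn they reached 7.317, 7.031 and 7.22. With the neuronal and microglial scores PSMB9 (-0.09), IFI44 (-0.004), XAF1, RE vs Control (-0.069), SV2B (0.166), NEUROD6 (0.326), CACNA2D1 (0.083), KCNA2 (0.046), APOC1 (-0.479), LIPA (-0.026), CTSZ, RE vs Control (-0.417), PRF1 (-0.492) and GRIA3 (0.509) reversed in RE vs Control, and ABCA13 (-0.478), LTF, PWE vs Control (-1.507) and HLA-DQA1 (-0.092) in PWE vs Control. Of 2-fold changes simulated at the real depth, spread and group sizes 61%, 48% and 42% were recovered in the 3 comparisons, and depth was not varied on its own.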

Other observations

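Some genes of lipid synthesis were lower and some of lipid efflux higher in RE than in Control, and whether the lists differ from each other was not tested. Of 16 Lipid and cholesterol synthesis genes 4 fell by edgeR (7 adjusted over the list alone, 11 without RE replicate 6), 5 by DESeq2 and 8 by voom. Among them were STARD4, a cholesterol carrier, at -1.01 ± 0.22 (adjusted p = 0.00129, lower in 24 of 25 libraries) and SREBF2, the regulator of cholesterol synthesis, at -0.57 ± 0.14 (lower in 25 of 25). Of 19 Lipid efflux and lysosome genes 7 rose by edgeR (9 adjusted over the list alone), 11 by DESeq2 and 8 by voom. Among them were APOC1, an apolipoprotein, at 2.58 ± 0.57 (20 of 25) and the lysosomal lipase LIPA at 1.12 ± 0.31 (22 of 25). The synthesis score passed (difference -0.53, adjusted p = 0.0299) and the efflux score did not (0.47, adjusted p = 0.113). Camera gave an adjusted p = 0.544 with an estimated correlation for each of these lists.

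Of 19 Hypoxia and glycolysis genes 10 fell in RE vs Control (11 adjusted over the list alone; 6 without Control replicate 9; adjusted p = 0.544 with an estimated correlation). By DESeq2 9 fell, and by voom 7 fell and 1 rose. The score difference of -0.45 did not pass (permutation test, adjusted p = 0.0936). VEGFA, a vessel growth factor, fell by 1.30 ± 0.26 on the log2 scale (adjusted p = 0.000494, lower in 25 of 25) and BNIP3 by 0.68 ± 0.15 (24 of 25). The smooth muscle genes MYH11 (-3.14 ± 0.60) and CNN1 (-2.46 ± 0.44) were lower in 23 of 25 libraries each, and by less without Control replicate 9 (-1.79 and -1.48).

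Scores of connective tissue were lower in RE than in PWE, but this rests on single libraries. The Fibroblast and meninges score differed by -1.16 (adjusted p = 0.0388, lower in 21 of 25), a call lost without PWE replicates 1, 4, 6 or 8 or RE replicates 10, 14, 15, 18 or 22 (up to 0.0955). The Extracellular matrix and scar score differed by -0.73 (adjusted p = 0.0425, lower in 19 of 25), lost without PWE replicates 1, 5, 6 or 8 or RE replicates 2, 10, 13, 14, 15, 18 or 22 (up to 0.112). Camera gave an adjusted p = 0.544 with an estimated correlation for each.

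No test of a hypothesis was added for these values.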
